A study of Rattus norvegicus with 21 samples.

How the data were processed

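Rat insulinoma cells, an insulin-secreting line derived from a beta cell tumour, were exposed for 24 h to inorganic arsenic (iAs, 1 µM), cadmium (Cd, 5 µM) or manganese (Mn, 25 µM), or left untreated, per the labels' protocols. Cells had been seeded 24 h earlier in 12-well plates. Polyadenylated RNA was sequenced in 4 libraries labelled untreated and 5 labelled iAs, made with a Kapa mRNA kit. Small RNA was sequenced in 3 libraries per group for all 4 groups, made with a TriLink CleanTag kit. The labels also give the tissue as liver, which does not match the named cell line. No label says that the libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

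The mRNA values are a signal of the authors: read counts per gene divided by DESeq2 normalization factors, named so in the labels of the deposited table. The submitters' processing notes name DESeq2, STAR and Salmon and the genome build rn6, without versions or roles. Low values cluster near 1 step per library, between 0.81 and 1.20 normalized counts per read, but spread around it, so whole reads were not recovered. The source of this spread was not tested. The small RNA values are RPMMM, a form of RPM in which the authors scaled the reads of each library mapped to microRNAs to a total of 1000000, per the labels and the column sums. Their low values are spaced by 0.127 to 0.169 RPMMM. Between 64.0% and 73.6% of low values in a library were whole multiples of that step within 0.0075 RPMMM, so whole reads were not recovered there either. The smallest value above 0 was worth about 10 reads, and lower entries are listed at 0. Planned count-based tests on recovered reads (edgeR, DESeq2) were therefore not run.

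Samples were grouped by the treatment named in their labels, and columns were matched to samples by the library code in the description. For 4 mRNA libraries the code in the title differs from that in the description, within the same group. Differences were tested with limma 3.58.1 in R 4.3.3 (limma-trend) on log2(value + 1), for genes with a mean of at least 10 normalized counts (14410 of 32750) and rows with a mean of at least 10 RPMMM (523 of 1186, of which 244 are forms with a shifted start). A log2 difference is on this log2(value + 1) scale, which damps changes of low genes, although a library at 0 can enlarge one. The 12 small RNA libraries shared 1 fit with 4 groups. The deviations of same-numbered iAs and Cd small RNA libraries from their group means correlated at 0.37, 0.46 and 0.18, each over 0.1. The labels give no pairing, and some libraries of different numbers correlated more strongly, such as untreated replicate 1 with Cd replicate 2 (0.69). Whether these numbers pair libraries is therefore uncertain. The main fit held no pairing, and a fit with a replicate block is given as an alternative. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Gene lists (20) and microRNA lists (7) were tested with camera at a preset correlation of 0.01 where at least 5 members were measured, adjusted over the lists, and again with an estimated correlation. A number stem in a microRNA list was also allowed to match the same number with the letter a, a choice made after the row names were seen. List counts are rows, and 36 tested rows hold the same values as another row because precursors share a mature sequence. The preset correlation takes such rows, and shifted forms of one microRNA, as nearly independent, so its p-values for microRNA lists can be too small. Symbols read as dates in 25 rows were left as they stand.

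The lists, the tests, the groups and the rule for named genes were fixed before the data were examined. The rule took the 6 largest rises and 6 largest falls among genes past the threshold with a symbol, a mean of at least 50 and no overlap between groups. It also took the 2 members with the smallest adjusted p per list, and a fixed set of beta cell, stress and marker genes. For each metal it took the 6 largest rises and 6 largest falls among microRNAs without overlap, and a fixed set of beta cell, stress and liver microRNAs. Hspa1b, one of the fixed genes, was not matched to a symbol here. Tkt, Slc30a1, Slc11a2, Slc39a10, Tfrc and miR-382-5p were named outside this rule, after their values were seen.

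On simulated values with the spread of the real libraries, the mRNA test (14410 genes) recovered 64.2% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 97.0% of those changed 4-fold, with 5 false calls among the unchanged genes. The small RNA test (523 rows, iAs against untreated) recovered 85% of rows changed 1.5-fold, 95% of those changed 2-fold and 100% of those changed 4-fold, with 1 false call. Genes and rows were simulated independently of each other. Differences shared by many rows of a library were therefore absent, and false calls in the real data may be more frequent.

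Alternatives covered blocks for replicate number and library code, pseudocount 5, other minimum values, other scalings, array weights, fits of 2 groups alone, summed forms of one microRNA arm, and leaving out each library. Host genes and neighbours of microRNA genes were taken from a RefSeq gene table of the assembly GRCr8, without strand; since the build differs, no coordinates are given. No genome sequence was used here, so microRNA target sites were not analysed here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.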

Results

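The mRNA and the small RNA of rat insulinoma cells, an insulin-secreting line, were measured after 24 h with or without metals. The mRNA table held 9 libraries (4 labelled untreated, 5 labelled iAs) with column totals between 51009800 and 55869159 normalized counts, worth about 44448381 to 65810640 reads as judged from the value of 1 read. The small RNA table held 12 libraries, 3 for each of untreated, iAs, Cd and Mn, of about 5903188 to 7898894 microRNA reads each. Ins1 was the most abundant gene in each mRNA library, at 2.32% to 3.90% of the total, and rno-mir-7a-1-5p the most abundant row in each small RNA library, at 10.1% to 11.8%.

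The mRNA comparison asked which genes differ between cells exposed to 1 µM iAs and untreated cells. Several genes of the oxidant response and the metallothionein gene Mt1 were lower in the libraries labelled iAs than in those labelled untreated. Hmox1 (ENSRNOG00000014117), which encodes the heme-degrading enzyme heme oxygenase 1, had 1739 ± 465 normalized counts (SD, n = 5) in the libraries labelled iAs and 14132 ± 1727 (SD, n = 4) in those labelled untreated, a log2 difference of -3.06 (SE 0.17, limma adjusted p = 8.5e-07). The metallothionein gene Mt1 (ENSRNOG00000038047) differed by -2.04 in log2 (SE 0.23, adjusted p = 8.5e-05), Nqo1 by -1.07 and Gclm by -1.06. The adhesion molecule gene Icam1 (ENSRNOG00000020679) at -3.82 and the chemokine gene Cxcl10 at -3.71 were lower as well. Among genes with a mean of at least 50 normalized counts and no overlap between the groups, the largest rises were in Txnip, a glucose-responsive inhibitor of thioredoxin, at 18621 ± 7275 normalized counts (SD, n = 5) against 2008 ± 181 (SD, n = 4), a log2 difference of 3.14 (SE 0.21), and in Cpne9, Prok2, Cilp2, Rasgrp2 and Tmem255b, at 3.01, 2.83, 2.63, 2.60 and 2.50. Beside Icam1, Cxcl10 and Hmox1, the largest falls under the same limits were in Majin (-2.88), Madcam1 (-2.59) and Qrich2 (-2.40).

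Of 14410 genes tested, 2181 were higher and 2140 lower in the libraries labelled iAs (limma, adjusted p under 0.05), 30.0% in all. Counts of called genes in the lists below are to be read against this share. Several lists, such as that of proteasome genes, lie under it. Of the called genes 3435 had no overlap between the groups, against 25.9% of all genes tested and 1.59% by chance. Here and below, calls and overlap rest on the same values, so a lack of overlap is no separate support for the calls. After rescaling to equal totals the split was 1787 higher and 2528 lower. Among the called genes, 1187 differed by more than 1.5-fold and 455 by more than 2-fold. All mRNA directions here and below, including rises and falls in gene lists, rest on the group labels of the mRNA libraries. Across 65 genes that hold a tested microRNA, the iAs differences of the mRNA and of the microRNA were negatively correlated (Spearman's rho = -0.52, two-sided permutation p = 2.0e-05, adjusted p = 1.2e-04 over 6 comparisons). This correlation is across genes, which are not independent replicates. The untreated libraries were all sequenced in lane 3 and the iAs libraries in lane 4, so lane and group cannot be told apart. The endings of the library codes also split the libraries. Within the libraries of the most common ending alone (2 untreated, 3 iAs), 1564 genes were higher and 1456 lower, and the other endings hold 1 library of each group, too few for a value.

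**Figure D1:**
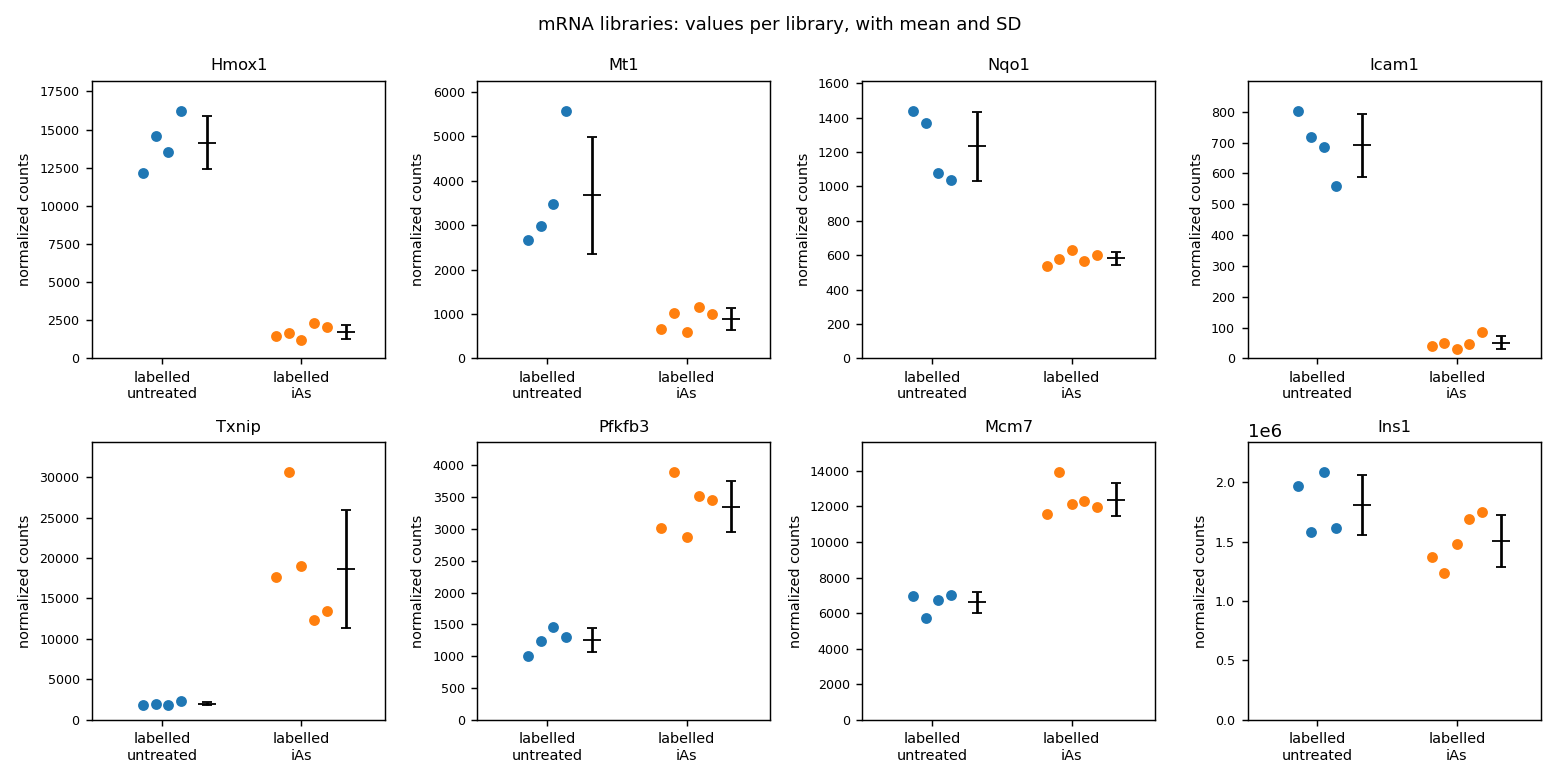
Normalized counts of 8 genes in each mRNA library (points), with the mean and SD of each group (bars) beside them. Hmox1, Mt1, Nqo1 and Icam1 do not overlap between the groups and are lower in the libraries labelled iAs, Txnip, Pfkfb3 and Mcm7 are higher without overlap, and Ins1 overlaps.

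Among 30 measured targets of NRF2, the transcription factor of the oxidant response, 16 fell and 1 rose, the pentose phosphate pathway gene Tkt (0.44), and 16 and 1 when adjusted over the list alone. Their median log2 difference was -0.40 (camera adjusted p = 1.2e-06), and adjusted p = 0.20 with an estimated correlation. Hmox1 and Gclm, a subunit of the enzyme that starts glutathione synthesis, had the smallest adjusted p. Of 10 metal response genes 4 fell and 3 rose, also when adjusted over the list alone (camera adjusted p = 0.74). The list's median was 0.10 while its mean was -0.16 and its test pointed down. Those that fell were the metallothionein genes Mt1 and Mt3 (-1.02), the zinc exporter gene Slc30a1 (-0.68) and the metal importer gene Slc11a2 (-0.35), and those that rose were the metal importer genes Slc39a14 (0.62) and Slc39a10 (0.37) and the transferrin receptor gene Tfrc (0.57). Of 11 genes of arsenic handling 5 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.73), and without untreated replicate 1 there were 3 rises and 4 falls. The list's median was 0.17 and its test pointed up while its mean was -0.06. Ahcy, an enzyme of the methylation cycle, rose by 0.48 in log2, and the glutathione transferase gene Gsto1 differed by -0.35.

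Inflammatory and NF-kB-related genes fell in 12 of 15 measured members and rose in 0, with 12 falls and 1 rise when adjusted over the list alone (median -0.94, camera adjusted p = 2.1e-07, and adjusted p = 0.20 with an estimated correlation). Icam1 and Cxcl10 had the smallest adjusted p among them. Glycolytic and hypoxia-responsive genes rose in 17 of 21 members and fell in 0, also when adjusted over the list alone (median 0.63, camera adjusted p = 3.3e-10, and adjusted p = 0.39 with an estimated correlation). Pfkfb3, a regulator of glycolysis, rose from 1248 ± 188 (SD, n = 4) to 3351 ± 408 (SD, n = 5) normalized counts, and Pkm differed by 0.63 in log2. Cell cycle genes rose in 16 of 33 members and fell in 0, with 17 rises when adjusted over the list alone (median 0.20, camera adjusted p = 3.5e-05, and adjusted p = 0.46 with an estimated correlation), led by the replication helicase subunit Mcm7 (0.91) and the spindle checkpoint kinase gene Bub1b (0.43). Cholesterol synthesis genes rose in 11 of 24 members and fell in 1, Tm7sf2 (-0.47), with 13 rises and 1 fall when adjusted over the list alone (median 0.20, camera adjusted p = 0.0016, and adjusted p = 0.39 with an estimated correlation). Hsd17b7 rose by 1.36 in log2. Among p53 targets 7 of 19 fell and 2 rose, with 8 falls and 2 rises when adjusted over the list alone (median -0.30, camera adjusted p = 0.024, and adjusted p = 0.20 with an estimated correlation), including the death receptor gene Fas (-1.37) and Bax (-0.61). The p53 falls numbered 4 without untreated replicate 1. Proteasome genes fell in 3 of 26 members and rose in 0, also when adjusted over the list alone (median -0.07, camera adjusted p = 0.024, and adjusted p = 0.81 with an estimated correlation), among them Psmc4 (-0.30) and Psmd4 (-0.19). Psmd4 lost its call without untreated replicate 1 (adjusted p = 0.0705) and without untreated replicate 3 (adjusted p = 0.0509), and the proteasome falls numbered 1 without untreated replicate 1 and 8 without untreated replicate 2.

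Beta cell identity genes went both ways, with 4 rises and 6 falls among 30, also when adjusted over the list alone (camera adjusted p = 0.62). The insulin genes were not called. Ins1 had 1508062 ± 216854 normalized counts (SD, n = 5) against 1811311 ± 252884 (SD, n = 4), adjusted p = 0.20, and Ins2 23114 ± 4532 against 23004 ± 5692, adjusted p = 0.95. Their sequences are similar, so the split of reads between them is uncertain. The transcription factor genes Pdx1 and Mafa differed by -0.05 (adjusted p = 0.68) and -0.16 (adjusted p = 0.19). The prohormone convertase gene Pcsk2 (-0.44) fell. Of 34 insulin exocytosis genes 6 rose and 8 fell, with 7 and 9 when adjusted over the list alone (camera adjusted p = 0.74), including Sytl4 at 0.70 and Exoc1 at -0.37. Their mean was 0.01 while their test pointed down. Glucagon transcript (Gcg) fell from 96799 ± 24631 (SD, n = 4) to 61075 ± 11878 (SD, n = 5), the 1 member called of 3 measured genes of other islet cells (2 without iAs replicate 2), also when adjusted over the list alone, too few for a list test.

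Heat shock genes rose in 3 of 18 members and fell in 1, also when adjusted over the list alone (camera adjusted p = 0.43), with Fkbp4 at 0.50 and Hsph1 at -0.28. Unfolded protein response genes rose in 4 of 23 and fell in 0, also when adjusted over the list alone (camera adjusted p = 0.097), with Pdia4 at 0.49 and Hsp90b1 at 0.33. Hspa5 differed by 0.30 and was not called (adjusted p = 0.063), but was called without iAs replicate 2 (0.40, adjusted p = 0.0028). Of 26 genes of the integrated stress response 5 fell and 0 rose, with 3 falls when adjusted over the list alone (camera adjusted p = 0.11, and adjusted p = 0.81 with an estimated correlation), including Atf5 (-0.85) and Cebpb (-0.98). Ddit3 (-0.78, adjusted p = 0.034) lost its call without each of untreated replicates 1, 3 and 4 and iAs replicates 1, 3, 4 and 5 (adjusted p between 0.0520 and 0.0767). Of 32 oxidative phosphorylation genes 3 rose and 3 fell, with 1 and 2 when adjusted over the list alone (camera adjusted p = 0.74), among them Ndufs1 at 0.25 and Ndufs8 at -0.34. Of 17 genes of microRNA processing 1 rose, the exporter gene Xpo5 (0.22), and 2 fell, with 1 rise and 0 falls when adjusted over the list alone (camera adjusted p = 0.50). Dgcr8 (-0.19, adjusted p = 0.043) lost its call without each library except untreated replicate 2 and iAs replicate 2 (adjusted p between 0.0559 and 0.133). Counts of these lists also moved without 1 library. Heat shock genes had 1 rise and 1 fall without untreated replicates 1 or 3 or iAs replicates 3, 4 or 5, and unfolded protein response genes 9 rises without iAs replicate 2. Falls in the integrated stress response numbered 3 without untreated replicates 1, 3 or 4 or iAs replicates 1, 3, 4 or 5, and 1 gene rose without untreated replicate 4. Oxidative phosphorylation genes had 1 rise and 2 falls without untreated replicate 1 or iAs replicate 5. They had 1 rise and 8 falls without untreated replicate 2, 5 rises and 2 falls without iAs replicate 1, and 1 rise and 4 falls without iAs replicate 4. MicroRNA processing genes had 1 rise and 0 falls without untreated replicates 1 or 3 or iAs replicates 4 or 5 (3 or 4 genes at an unadjusted p under 0.05 in limma).

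Markers of other tissues were measured as well. Not all were low, since Thy1 had 11389 ± 1541 normalized counts (SD, n = 4) in the libraries labelled untreated. Of 8 hepatocyte genes 1 rose and 2 fell, Fgb at -1.34 and Ass1 at -0.45, also when adjusted over the list alone (camera adjusted p = 0.62; the median was 0.01 while the mean was -0.16 and the test pointed down), and Alb was at 0 in the libraries labelled untreated and at most 2.01 normalized counts in those labelled iAs. Of 6 fibroblast, endothelial and immune genes 3 fell, including Cd74 (-3.05, from 80.7 ± 20.6 to 13.5 ± 9.74 normalized counts, and -2.24 without iAs replicate 2, which was at 0) and Thy1 (-0.54), and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.43), with 2 falls and 0 rises without each untreated replicate or iAs replicate 5 (4 or 5 genes at an unadjusted p under 0.05 in limma). Of 4 acinar and duct genes Sox9 rose, from 84.5 ± 19.5 to 445 ± 75.7 normalized counts (log2 difference 2.40), and Rbpjl fell (-0.57), also when adjusted over the list alone, too few for a list test (median -0.12, mean 0.40). Rbpjl lost its call without each library except untreated replicate 1 and iAs replicate 1 (adjusted p between 0.0531 and 0.101).

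**Figure D2:**
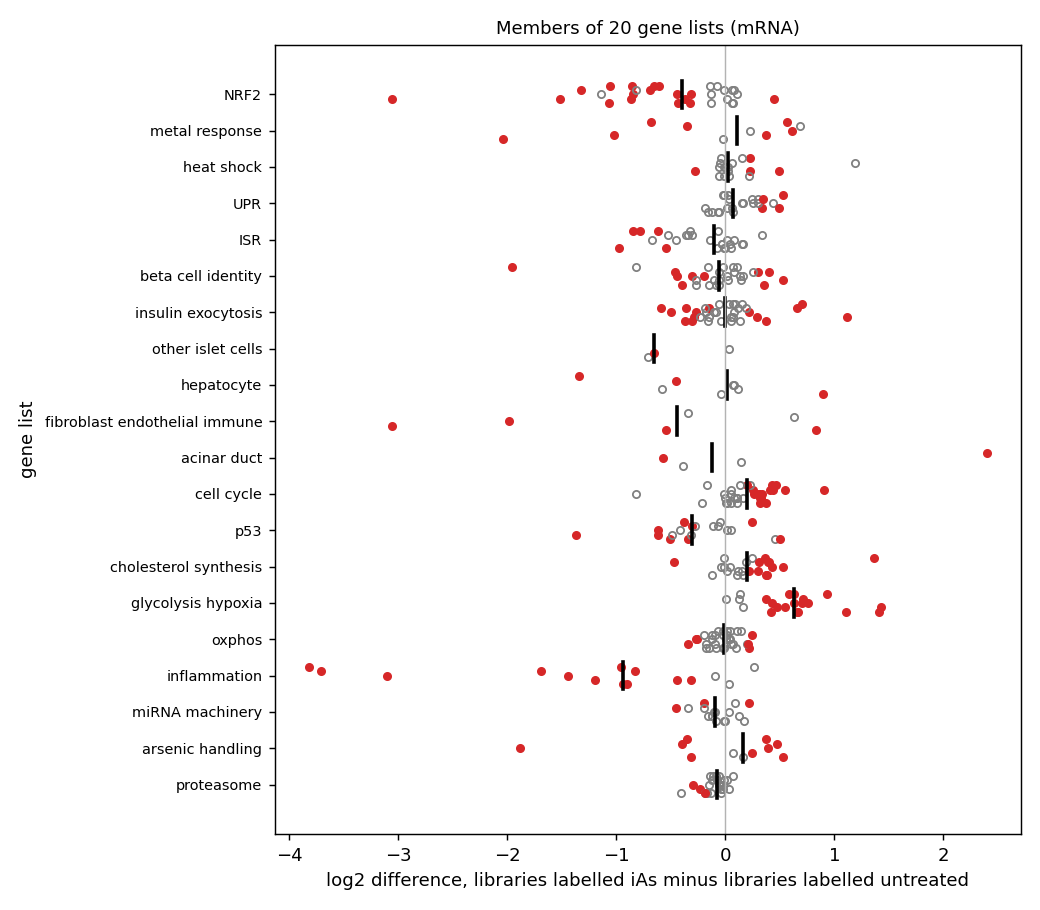
Log2 difference of each measured member of the 20 gene lists between libraries labelled iAs and libraries labelled untreated (filled points pass the adjusted p threshold, open points do not), with the list median as a vertical bar. The medians of the inflammation list (-0.94) and the glycolysis and hypoxia list (0.63) lie farthest from 0 on either side among the lists with a test.

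The small RNA comparison of iAs with untreated cells asked which microRNAs change with 1 µM iAs. miR-146a-5p, a microRNA known to be induced through NF-kB, rose from 15.1 ± 1.73 to 28.9 ± 1.27 RPMMM (SD, n = 3 each; log2 difference 0.90, SE 0.12, adjusted p = 3.1e-04). miR-708-5p fell from 83.8 ± 3.64 to 50.2 ± 2.31 RPMMM (log2 difference -0.73, SE 0.09, adjusted p = 3.1e-04), and the hypoxia-responsive miR-210-3p fell from 580.0 ± 76.8 to 351 ± 78.0 (-0.74, SE 0.13, adjusted p = 0.0024). Further falls were in miR-541-5p (-0.84), miR-410-3p (-1.11), miR-369-3p (-0.91) and a form of miR-409a-3p with a shifted start (-1.29). Rises included shifted forms of miR-29b-1-5p (0.94), of the miR-29b-2 and miR-29b-3 5p arms, whose rows hold the same values (0.51), and of miR-320-3p (0.85), and miR-671 (0.47). In all, 14 rows were higher and 30 lower of 523 tested, and 10 of these differed by more than 1.5-fold. The 44 rows had no overlap between the groups, against 29.3% of all rows and 10% by chance. The rise of miR-146a-5p and the fall of miR-210-3p ran opposite to the NF-kB-related and hypoxia-responsive mRNA lists in the libraries labelled iAs. Whether they are related was not tested.

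The split of these calls depended on the scaling, with 24 higher and 24 lower after median-of-ratios rescaling. The count was 27 without untreated replicate 2, 80 without untreated replicate 3, 24, 77 and 21 without iAs replicates 1, 2 and 3, 28 without Cd replicate 3 and 29 without Mn replicate 2; leaving out a library left 2 in its group. The calls of miR-146a-5p, miR-708-5p, miR-210-3p, miR-541-5p, miR-410-3p, miR-369-3p and the shifted forms of miR-409a-3p and miR-29b-1-5p held in each alternative that gave them a value. That of the miR-320-3p form was lost without untreated replicates 1 and 2, iAs replicates 1 and 3, Cd replicate 3 and Mn replicate 3 (adjusted p between 0.0565 and 0.146), with quantile normalization (0.0589) and without a filter (0.0679). That of miR-671 was lost without untreated replicates 1 and 2, iAs replicates 1 and 3, Cd replicate 1 and each Mn replicate (adjusted p between 0.0533 and 0.143) and without a filter (0.0653), and those of the miR-29b-2 and miR-29b-3 forms without iAs replicates 1 and 3 (adjusted p = 0.0661 and 0.0525).

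The comparison of Cd with untreated cells asked the same of 5 µM Cd, with which 19 rows were higher and 36 lower than in untreated cells, 4 of them by more than 1.5-fold. miR-195-3p fell from 18.8 ± 1.94 to 10.2 ± 1.72 RPMMM (SD, n = 3 each; log2 difference -0.83, SE 0.12, adjusted p = 0.0057) and its cluster neighbour miR-497-5p by 0.51 in log2. Rows of miR-101a-3p (-0.56 and -0.54), miR-101b-3p (-0.48) and a shifted form of miR-30a-5p (-0.48) fell. The activity-regulated miR-212-3p rose from 147 ± 17.5 to 209 ± 10.5 RPMMM (0.51), and miR-490-5p (0.71), miR-194-2-3p (0.66), a shifted form of miR-29b-1-5p (0.59) and shifted forms of let-7d-5p (0.54) and let-7e-5p (0.47) rose. Of the called rows 53 had no overlap between the groups, against 30.4% of all rows and 10% by chance. The count fell to 0 in a limma fit of the 2 groups alone, where 130 rows had an unadjusted p under 0.05. It was 1 without untreated replicate 1, 1 without untreated replicate 2, 93 without untreated replicate 3, 1 without Cd replicate 1, 0 (110 at an unadjusted p under 0.05) without Cd replicate 3, 36 without iAs replicate 3, and 31 and 30 without Mn replicates 2 and 3. Without Cd replicate 3 all 12 named calls were lost (adjusted p between 0.0568 and 0.164). Without untreated replicate 1, untreated replicate 2 or Cd replicate 1, miR-195-3p was the 1 row still called, and 10 named calls were lost in each case (adjusted p up to 0.220, 0.0903 and 0.158), while 1 more, the miR-30a-5p form or without Cd replicate 1 the let-7e-5p form, fell under the minimum mean. Of the named calls, that of miR-490-5p was also lost without untreated replicate 3, Cd replicate 2 and Mn replicates 2 and 3, those of the miR-30a-5p and miR-101b-3p forms without iAs replicate 3 and each Mn replicate, and that of the let-7e-5p form without iAs replicates 1 and 3 and Mn replicates 1 and 3 (adjusted p between 0.0508 and 0.0654).

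The comparison of Mn with untreated cells asked the same of 25 µM Mn, with which 13 rows were higher and 26 lower than in untreated cells, 7 of them by more than 1.5-fold. miR-582-3p fell from 154 ± 9.67 to 100.4 ± 6.02 RPMMM (SD, n = 3 each; log2 difference -0.61, SE 0.11, adjusted p = 0.0091), and its shifted form by 0.70 in log2. miR-101a-3p (-0.65), miR-137-3p (-0.76), miR-188-5p (-0.54) and miR-210-3p (-0.53) fell. miR-125b-1-3p rose by 0.80 in log2 (SE 0.15, adjusted p = 0.0106), miR-346 and its shifted form by 0.64 and 0.56 in log2, miR-7b by 0.54, and shifted forms of miR-342-5p and let-7e-5p by 0.56 and 0.51. Of the called rows 38 had no overlap between the groups, against 28.7% of all rows and 10% by chance. The count was 6, 18 and 89 without untreated replicates 1, 2 and 3 (the last with 51 higher and 38 lower, so most were then rises), 9, 16 and 4 without Mn replicates 1, 2 and 3, 22 without iAs replicate 3 and 21 without Cd replicate 3. Both miR-582-3p rows stayed called in each alternative. Of the other 10 named calls, 9, 6 and 1 were lost without untreated replicates 1, 2 and 3, and 7, 5 and 10 without Mn replicates 1, 2 and 3 (adjusted p between 0.0509 and 0.190). Calls of miR-7b, miR-137-3p and the let-7e-5p form were also lost without iAs replicate 3 and Cd replicate 3, those of miR-7b and the let-7e-5p form without iAs replicate 1, and those of miR-7b and miR-137-3p without Cd replicate 1 (adjusted p between 0.0504 and 0.0697).

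**Figure D3:**
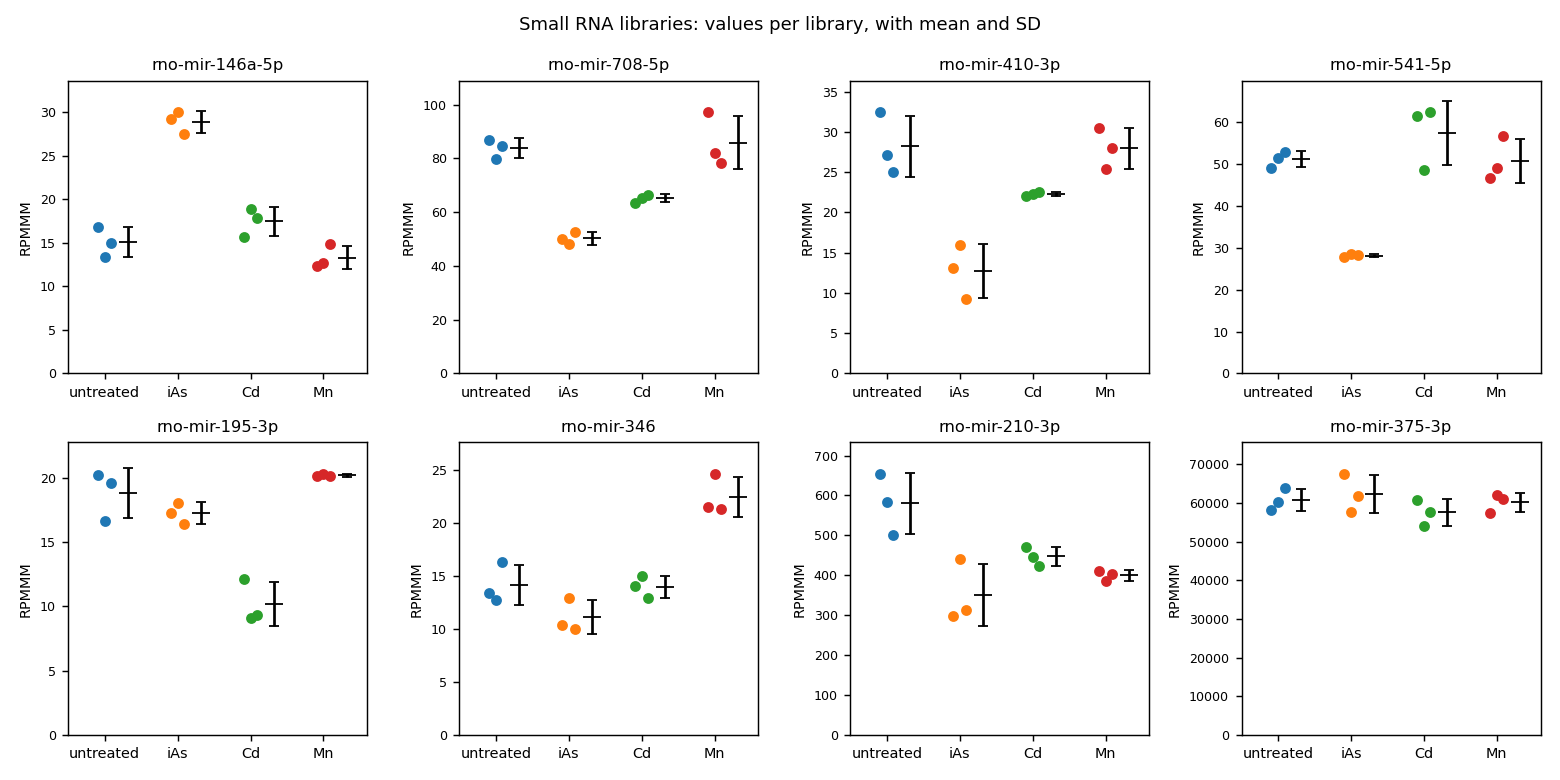
RPMMM of 8 microRNAs in each small RNA library (points), with the mean and SD of each group (bars) beside them. miR-146a-5p is higher, and miR-708-5p, miR-410-3p and miR-541-5p lower, in the iAs libraries without overlap with untreated, miR-195-3p is lower with Cd, miR-346 is higher with Mn, and miR-375-3p overlaps in all groups.

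The most abundant beta cell microRNAs were not called with any metal. miR-375-3p had 60803 ± 2962 RPMMM in untreated cells and 62333 ± 4973, 57568 ± 3414 and 60158 ± 2454 with iAs, Cd and Mn (SD, n = 3 each), and the miR-7a-5p rows differed by at most -0.10 in log2. miR-204-5p fell with Mn (-0.29, adjusted p = 0.030) and miR-184 rose with Cd (0.37, adjusted p = 0.043). The call of miR-204-5p was lost without untreated replicate 1, iAs replicate 3 and Mn replicates 1 and 3 (adjusted p between 0.0538 and 0.138), and that of miR-184 without each library except iAs replicates 1 and 2 (adjusted p between 0.0505 and 0.195). miR-21-5p, miR-34a-5p, miR-200c-3p and miR-29a-3p were not called with any metal, and with iAs miR-200c-3p differed by 0.19 and miR-29a-3p by 0.30 (both adjusted p = 0.0680). Leaving out a library added some calls: with iAs, miR-200c-3p without untreated replicate 3 or Cd replicate 1 (adjusted p = 0.0381 and 0.0478), miR-184 without untreated replicate 2 (0.0232) and miR-29a-3p without untreated replicate 1 (0.0258). With Cd, miR-210-3p was called without untreated replicate 3 or iAs replicate 2 (0.0297 and 0.0228), and miR-21-5p without untreated replicate 3 with Cd (0.0345) and with Mn (0.0360). miR-122-5p had no row among those tested. Of 51 rows of the beta cell list 0 were called with iAs, 1 rose and 3 fell with Cd, and 1 rose and 2 fell with Mn (camera adjusted p = 0.55, 0.044 and 0.096, the call with Cd being lost at adjusted p = 0.47 with an estimated correlation). Over all rows tested, 8.4%, 10.5% and 7.5% were called with iAs, Cd and Mn, against which the counts of the microRNA lists are to be read. Adjusted over the beta cell list alone the counts were 0, 1 rise and 3 falls, and 0 rises and 2 falls. With Cd the count of this list was 0 in limma without untreated replicates 1 or 2, Cd replicates 1 or 3 or any Mn replicate (between 5 and 14 rows at an unadjusted p under 0.05). It was 1 fall without iAs replicate 3 and 5 falls without untreated replicate 3. With Mn it was 1 fall without untreated replicate 1, iAs replicate 3 or Mn replicates 1 or 3, and 5 falls without untreated replicate 3. With iAs it was 1 rise without untreated replicate 2, 5 falls without untreated replicate 3 and 3 falls without iAs replicate 2.

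With iAs, 4 of 16 rows of the miR-29 family rose, 6 when adjusted over the list alone (median 0.31, camera adjusted p = 4.0e-07, and adjusted p = 0.23 with an estimated correlation). Rows of the miR-17-92 and related clusters fell in 4 of 26 with iAs and in 3 with Cd, 6 and 4 when adjusted over the list alone (medians -0.23 and -0.21, camera adjusted p = 0.0028 and 6.6e-04, and adjusted p = 0.23 and 0.33 with an estimated correlation), and 0 were called with Mn (camera adjusted p = 0.29). Of 75 let-7 rows 10 rose with Cd and 5 with Mn, 13 and 10 when adjusted over the list alone, where 1 also fell with Mn. With iAs 1 rose and 1 fell, and 0 when adjusted over the list alone. The let-7 medians were 0.12, 0.15 and 0.18 with iAs, Cd and Mn (camera adjusted p = 2.0e-05, 2.3e-08 and 2.0e-09, and adjusted p = 0.36, 0.38 and 0.49 with an estimated correlation). Many let-7 rows are shifted forms or precursor copies of the same few microRNAs, so the first 3 of these p-values can be too small. Of 10 miR-200 rows 2 rose with iAs, 1 with Cd and 0 with Mn (camera adjusted p = 0.042, 0.17 and 0.39, the first of which was adjusted p = 0.23 with an estimated correlation); adjusted over the list alone 4 rose and 1 fell with iAs and 1 rose with Cd. With Cd 1 row of the miR-29 family rose, also when adjusted over the list alone, and with Mn 0 were called (camera adjusted p = 0.34 and 0.14). These family counts depended on single libraries. With Cd, all 4 families had 0 called rows in limma without untreated replicate 1, untreated replicate 2, Cd replicate 1 or Cd replicate 3. In these fits 17, 25, 19 and 20 let-7 rows and 7, 8, 7 and 10 of the miR-17-92 rows had an unadjusted p under 0.05 (1 to 4 of the miR-200 and 1 or 2 of the miR-29 rows). Rises of let-7 with Cd numbered 19 without untreated replicate 3 and 6 without Mn replicates 2 or 3. Falls of the miR-17-92 rows with Cd numbered 6 without untreated replicate 3 or iAs replicate 2. The miR-200 rise with Cd was also lost without untreated replicate 3, iAs replicates 1 or 3, Cd replicate 2 and Mn replicates 1 or 2 (4 rows at an unadjusted p under 0.05). With Mn, let-7 rises numbered 0 in limma without untreated replicates 1 or 2, Cd replicate 3 or any Mn replicate (17 to 27 rows at an unadjusted p under 0.05). They numbered 3 without iAs replicate 1, 2 without iAs replicate 3 or Cd replicate 1, and 21 without untreated replicate 3. Without untreated replicate 3 the miR-17-92 rows had 1 rise and 3 falls and the miR-29 family 3 rises with Mn. With iAs, miR-29 rises numbered 7 without untreated replicate 1 and 1 without iAs replicates 1 or 3. Falls of the miR-17-92 rows with iAs numbered 1 without untreated replicate 2 or iAs replicates 1 or 3, 2 without Cd replicate 3 or any Mn replicate, and 7 without iAs replicate 2. The miR-200 rises with iAs numbered 1 without untreated replicates 1 or 3 or Mn replicate 1. They numbered 0 without untreated replicate 2, any iAs replicate, Cd replicates 2 or 3 or Mn replicate 2 (4 or 5 rows at an unadjusted p under 0.05). With iAs, let-7 rows had 1 fall alone without untreated replicate 1, 12 rises and 2 falls without untreated replicate 3, and 9 rises and 3 falls without iAs replicate 2. They had 0 calls without untreated replicate 2, iAs replicates 1 or 3, Cd replicate 3 or any Mn replicate (10 to 17 rows at an unadjusted p under 0.05).

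Of 45 rows of stress and inflammation microRNAs 2 rose and 5 fell with iAs, 1 rose and 1 fell with Cd, and 1 rose and 2 fell with Mn (camera adjusted p = 0.55, 0.34 and 0.14). Adjusted over the list alone there were 3 rises and 6 falls with iAs and the same counts as above with Cd and Mn. Of 11 rows of liver, blood and muscle microRNAs 0 were called with iAs, 1 rose with Cd and 0 were called with Mn (camera adjusted p = 0.53, 0.068 and 0.29), and 2 rises, 3 rises and 1 fall when adjusted over the list alone. The median of this list with iAs was -0.04, while its test pointed up and its median after quantile normalization was 0.03. The Cd counts of both lists were 0 in limma without untreated replicates 1 or 2 or Cd replicates 1 or 3 (9 or 10 stress rows and 2 to 5 liver, blood and muscle rows at an unadjusted p under 0.05). Without untreated replicate 3 they were 4 rises and 3 falls, and 2 rises, and without iAs replicate 2 the first was 2 rises and 2 falls. With iAs, stress rows had 5 rises and 6 falls without untreated replicate 3 and 1 rise and 2 falls without iAs replicate 3. The liver, blood and muscle list had 1 rise with iAs without untreated replicate 1 or Mn replicate 3. With Mn, stress rows had 0 calls without untreated replicate 1 or Mn replicate 3 (8 and 7 at an unadjusted p under 0.05) and 1 rise without Mn replicate 1. The liver, blood and muscle list had 1 fall with Mn without Cd replicate 2.

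The metals were also compared with each other, to ask where their effects differ. Between iAs and Cd, 3 rows were higher and 12 lower with iAs, 6 of them by more than 1.5-fold. miR-146a-5p was higher with iAs than with Cd (0.70, SE 0.12, adjusted p = 0.0051), the miR-409a-3p form was lower (-1.37), and miR-195-3p was lower with Cd (0.72 for iAs against Cd). Between iAs and Mn, 38 rows were higher and 51 lower with iAs, 27 of them by more than 1.5-fold. These included miR-146a-5p (1.07), miR-708-5p (-0.76), miR-346 (-0.96) and miR-29a-3p (0.53). Between Cd and Mn, 19 rows were higher and 20 lower with Cd, 6 of them by more than 1.5-fold, and miR-195-3p (-0.94) and miR-125b-1-3p (-0.86) were lower and miR-212-3p (0.62) higher with Cd. These microRNAs kept their calls in each alternative that gave them a value. Some other microRNAs named above, such as miR-541-5p for iAs against Cd and against Mn, kept theirs too, and others did not. The doses differed (1, 5 and 25 µM), so the exposures used were compared and not matched doses. All 15, 89 and 39 called rows had no overlap between the groups, against 21.6%, 35% and 24.7% of all rows and 10% by chance.

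The split of iAs against Cd became 3 and 6 after median-of-ratios rescaling and 8 and 9 after quantile normalization. Its count was 8 without untreated replicate 2, 8 and 5 without iAs replicates 1 and 3, 6 and 5 without Cd replicates 2 and 3, and 9 without Mn replicate 2. For iAs against Mn it was 59 without iAs replicate 3, and 54 and 55 without Mn replicates 1 and 3. For Cd against Mn it was 16 and 8 without Cd replicates 1 and 3, and 4, 20 and 16 without Mn replicates 1, 2 and 3. With quantile normalization 41 rows were higher and 39 lower for iAs against Mn. With a replicate block, 3 rows were higher and 5 lower for iAs against Cd, and miR-708-5p was not called there (adjusted p = 0.0783).

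Some of the other named microRNAs called between metals lost their calls in at least 1 alternative. Between iAs and Cd these were miR-410-3p (4 alternatives, among them without iAs replicate 3 and Cd replicates 2 and 3), miR-497-5p (4, without iAs replicates 2 and 3 and Cd replicates 2 and 3) and miR-708-5p (14, among them without untreated replicate 2, each iAs replicate, each Cd replicate and Mn replicate 2), with adjusted p between 0.0518 and 0.188 without these libraries. Between iAs and Mn they were miR-137-3p (11, among them without untreated replicate 2, iAs replicates 2 and 3, Cd replicates 1 and 3 and each Mn replicate), miR-671 (6, among them without iAs replicates 1 and 3 and each Mn replicate), miR-101a-3p (4, among them without iAs replicate 2 and Mn replicates 1 and 3), miR-204-5p (4, without iAs replicates 1 and 3 and Mn replicates 1 and 3) and miR-125b-1-3p (1, without Mn replicate 3), with adjusted p between 0.0506 and 0.164. Between Cd and Mn they were miR-7b (8, among them without iAs replicate 3, Cd replicates 1 and 3 and each Mn replicate), miR-497-5p (7, among them without each Cd and each Mn replicate), miR-188-5p (5, without each Cd replicate and Mn replicates 1 and 3) and miR-708-5p (3, without Cd replicates 1 and 3 and Mn replicate 1). miR-490-5p (without Cd replicate 1 and Mn replicate 1), miR-346 and the miR-582-3p form (each without Cd replicate 3 and Mn replicate 1) and the miR-346 form (without Mn replicates 1 and 3) lost theirs in 2 each, with adjusted p between 0.0503 and 0.172 for Cd against Mn.

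The 3 metals were compared with the same untreated libraries. iAs and Cd shared 5 higher and 10 lower rows, where independent lists would share 0.51 and 2.07, iAs and Mn shared 0 and 3 (0.35 and 1.49 independent) with 2 in opposite directions, and Cd and Mn shared 5 and 10 (0.47 and 1.79 independent). No row was called in the same direction with all 3 metals. The Cd list held at most 1 row without untreated replicate 1, untreated replicate 2, Cd replicate 1 or Cd replicate 3, so the counts it shares would then be at most 1. Across rows, which are not independent replicates, the log2 differences correlated at r = 0.68 for iAs and Cd, 0.38 for iAs and Mn and 0.62 for Cd and Mn. Simulated unchanged groups against shared controls gave mean r of 0.46, 0.46 and 0.48, and 95% of simulated values lay between -0.48 and 0.93, -0.38 and 0.93, and -0.41 and 0.93. The covariances were 0.041, 0.023 and 0.035, against simulated covariances of 0.0096, 0.0093 and 0.0097. The 3 control libraries could not be split, so part of the excess may come from the shared controls.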

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

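Among 112 sets of values, 1 per named gene and mRNA group, 6 had a library far from the others of its group, and about 5.6 would be found by chance, since chance singles out about 1 in 20 groups. Untreated replicate 4 stood high for Atf5 (41879 normalized counts, the next at 32396), Gcg (133457, the next at 86935), Hsd17b7 (94.6, the next at 56.2) and Gsto1 (21958, the next at 18515). Untreated replicate 2 stood low for Fgb (493, the next at 668). Replicate 2 of the libraries labelled iAs stood low for Thy1 (5782, the next at 8199). Each of these libraries carries a code ending other than the most common. Untreated replicate 4 and iAs replicate 2 share an ending, and their deviations correlated at 0.17, the highest of any mRNA pair across the groups. Whether the library code or anything else explains these values was not tested.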

How the results depend on the processing

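The mRNA count in the libraries of the most common code ending, the list tests under other scalings, pseudocount 5 and the replicate block, and rescaling to the mean total instead of a fixed total were chosen after the data were seen. No call of a named gene, microRNA or gene list reversed in any alternative run for it. The mRNA count lay between 3020 and 5360 in the alternatives other than the replicate block, and between 3423 and 4068 without 1 library. Replicate numbers showed no sign of pairing the mRNA libraries, and whether they pair the small RNA libraries is uncertain. Deviations of same-numbered mRNA libraries correlated between -0.04 and 0.03. Those of same-numbered small RNA libraries, outside iAs with Cd, correlated between -0.62 and 0.28. They were 0.04, 0.18 and 0.13 for Cd with Mn, and 0.14, 0.28 and -0.13 for iAs with Mn. Of mRNA libraries 0 of 8, and of pairs of a small RNA library and another group 17 of 36 (those of iAs and Cd included), correlated best with their own number. With a replicate block the mRNA count was 2761 (2705 shared with the 4321), Mn 23 and iAs against Cd 8. With it Rbpjl (adjusted p = 0.139), Dgcr8 (0.160), Psmd4 (0.0740), Ddit3 (0.0713) and Ndufs1 (0.0697) were not called, nor were miR-184 and the let-7e-5p form with Cd (both 0.0573), miR-7b (0.0505), miR-204-5p (0.0514) and the let-7e-5p form (0.0555) with Mn, and miR-708-5p for iAs against Cd (0.0783). It changed no other call of a named gene or microRNA. Fits of 2 groups alone gave 25 rows for iAs, 0 for Cd and 8 for iAs against Cd. Without a filter Cd gave 20 and Mn 18, where more rows were tested. With quantile normalization Cd gave 21 and Mn 24. With a mean of at least 50, iAs against Cd gave 3, iAs against Mn 52 and Cd against Mn 25, where fewer rows were tested. Median-of-ratios rescaling gave 9 for iAs against Cd. Without 1 library in turn the counts ranged from 21 to 80 for iAs, 0 to 93 for Cd, 4 to 89 for Mn, 5 to 18 for iAs against Cd, 54 to 103 for iAs against Mn and 4 to 48 for Cd against Mn. The cause of these shifts was not tested beyond the number of rows and libraries. Leaving out a library leaves 2 in its small RNA group. It ended 68 calls of named microRNAs with Cd, 52 with Mn and 18 with iAs, and 23 of named mRNA genes, counted over genes and libraries. Hspa5 was also called with either code block (adjusted p = 0.0161 and 0.0198), with array weights (0.0275) and within the most common code ending (0.0493), and Mafa with the title code block (0.0356). Xpo5 was not called after rescaling to equal totals (adjusted p = 0.0598), and Xpo5, Ndufs1, Rbpjl and Psmd4 were not called within the most common code ending (adjusted p = 0.140, 0.0766, 0.346 and 0.0520). Without a filter Rbpjl (0.0629) and Dgcr8 (0.0535) were not called. The list of the integrated stress response was called with a block for the library code (camera adjusted p = 0.019) and not without it (camera adjusted p = 0.11), both at the preset correlation. Without the block and with an estimated correlation its camera adjusted p was 0.81. With iAs, miR-29a-3p and miR-184 were called after median-of-ratios rescaling (0.0260 and 0.0421) and with summed arms (0.0479 and 0.0345), and miR-200c-3p with a mean of at least 50 (0.0497) and with summed arms (0.0479). With Cd, miR-184, miR-490-5p and the forms of let-7e-5p, miR-101a-3p, miR-30a-5p and miR-101b-3p were not called without a filter or with quantile normalization (adjusted p between 0.0543 and 0.155). With Mn, miR-7b, miR-204-5p and the let-7e-5p form were not called without a filter, with quantile normalization or in a fit of 2 groups, miR-137-3p in the first 2 of these, and miR-210-3p and the forms of miR-346 and miR-342-5p without a filter (adjusted p between 0.0523 and 0.10). Count tests on whole reads were not run, since reads were not recovered.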

Other observations

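The host gene values of the other comparisons, the tests of scaling and of single untreated libraries, and all tests of the miR-410 cluster were chosen only after their results or the pattern had been seen.

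MicroRNAs of 1 cluster of 42 neighbouring microRNA genes moved together with iAs. Its 5 rows that passed the filter, miR-382-5p and the rows of miR-369-3p, miR-409a-3p, miR-410-3p and miR-541-5p named above, all fell (median log2 difference -0.91, from -1.29 to -0.55, camera p = 3.0e-07, and p = 7.3e-04 with an estimated correlation). With Cd 0 of the 5 rows were called in limma (median 0.05), and with Mn 1 rose, miR-382-5p (median -0.01). Tested directly, 4 of the 5 were lower with iAs than with Cd and 5 of 5 lower than with Mn. The rows are of low abundance, with a median of 22.8 RPMMM.

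The cluster's median was -0.88 in the higher of 2 rescalings, by median of ratios and by quantiles. These moved the median of all tested rows with iAs only from -0.024 to 0.0094 and -0.0045. A scaling difference of that size is too small for the cluster's fall, but the 2 rescalings cannot exclude a larger one. The cluster's median was at most -0.85 without each untreated library. This cannot decide whether 1 untreated library sets the difference. The rows were called and did not overlap between the groups, so the sign could not turn. A response of the cluster to iAs may explain its fall, as a hypothesis found and tested on the same libraries.

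Of 30 NRF2 targets 16 were lower and 1 higher in the mRNA libraries labelled iAs (the list's call was lost at adjusted p = 0.20 with an estimated correlation), and the metallothionein genes Mt1 and Mt3 were lower, whereas arsenic is known to activate NRF2 and induce metallothioneins. The median of the NRF2 list was -0.41 in the higher of 2 rescalings, to equal totals and by quantiles. These moved the median of all tested genes only from -7.0e-04 to -0.034 and 6.8e-04. A scaling difference of that size is too small for the list's fall, but the 2 rescalings cannot exclude a larger one. A candidate explanation is that the mRNA and small RNA libraries carry opposite group labels, in either assay: over 65 genes that hold a tested microRNA, the differences were negatively correlated across genes (Spearman's rho = -0.52, permutation p = 2.0e-05, without Mcm7, whose values had been seen; over 66 genes rho = -0.53, permutation p = 1.0e-05, the smallest it can give, Pearson's r = -0.36, permutation p = 0.00598, and r = -0.32, permutation p = 0.00712, without the 2 farthest genes), and 44 of 66 hosts differed in the opposite direction to their microRNAs, as did 8 of 8 microRNA genes called in both assays, 3 of them in Mcm7 and 1 of these by only -0.06 over its arms. This cannot establish an exchange, since rho was also negative for Cd against untreated (-0.38), Cd against Mn (-0.38) and iAs against Mn (-0.39, adjusted p = 0.00303 for each), where the mRNA values stayed those of iAs, though not past the threshold for iAs against Cd (-0.23, adjusted p = 0.0850) and Mn against untreated (-0.04, adjusted p = 0.755). A fall with iAs in these cells was not tested and stays open, and lane and group cannot be told apart.

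For the mRNA comparison, 1 of 100 splits of the 9 libraries, the real one, gave as many as 4321 genes. The highest other gave 862, so a chance division of the libraries is an unlikely source of the count. Lane and group divide the libraries alike, so the splits cannot tell them apart. The small RNA comparisons have 10 splits of 6 libraries each, too few for a share under 0.05. The real split and the highest other gave 44 and 36 rows for iAs, 55 and 53 for Cd, 39 and 0 for Mn, 15 and 0 for iAs against Cd, 89 and 0 for iAs against Mn, and 39 and 0 for Cd against Mn.

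The untreated small RNA replicate 1 lay at -6.76 on the first principal component, where the other 11 libraries lay between -2.52 and 3.63.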
